A study of Arabidopsis thaliana with 7 samples.

How the data were processed

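Gene expression was measured in Arabidopsis flowers of stages 1 to 14 with 7 single-colour Affymetrix arrays. Each of the 7 groups holds 1 array: wild-type Columbia flowers untreated, sprayed with a mock solution or sprayed with the auxin indole-3-acetic acid (IAA), and flowers of 2 mutant genotypes either untreated or sprayed with IAA. The mutations lie in ARF6 and ARF8, which encode auxin response factors. The mutants are called here the double mutant (arf6 arf8) and the third genotype. The sample labels write the third genotype as arf6/arf6 ARF8/arf8, while the series text gives the heterozygous gene as ARF6, so which of the genes was heterozygous stays open. The labels give the IAA dose as 10 µM and the series text as 10 mM, and this too stays open. The spray held 1% methanol and 0.05% Tween-20, and flowers were collected 30 minutes later per the series text. Untreated plants were not sprayed, and a mock array was used here for wild type alone, so IAA against untreated includes the effect of the spray.

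The deposited values are linear intensity signals, and MAS5 is named in the submitters' processing notes. The deposited intensity values were never negative, and each array had a 2% trimmed mean of 500 in the units of the file, so the authors' scaling was kept. The scaling factors, the detection calls and the masks are not given in the sources used here.

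Of the probe sets that are not Affymetrix controls, 13513 carried 1 gene symbol in the platform annotation of 2016, 503 carried several and 8730 had no gene listed. Symbols and locus codes were updated through the RefSeq table of assembly TAIR10.1, which was used for names and neighbours only. A probe set without a listed gene is unnamed here, not without a gene. ARF6 and ARF8 are among the genes not listed, so the level of either could not be given and the genotype labels were not checked on the mutated genes.

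Intensities were floored at the 25th percentile of all values (64.9) and taken to log2. Probe sets were kept where the highest of the 7 arrays exceeded the 50th percentile (248.1), which left 13021 for the test. A linear model with genotype and treatment as additive terms was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). It had 2 residual degrees of freedom and a prior worth 4.945, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. A further model with a term for IAA in the double mutant had 1 residual degree of freedom. Because no group has a repeat array, a difference between 2 arrays has no test from repeats of its own. The p-values measure how well the genotypes agree on a treatment difference, or the treatments on a genotype difference, and they assume that these effects add. The mock coefficient rests on 1 array that adds nothing to the residual spread, so its p-values use the spread of the other 6 arrays and assume that it varies like them. Fold values are on the floored scale, and where all arrays of a side lay below the floor the fold is given as "at least", for mock from the ratio of the mock and untreated arrays. The number of arrays limits the precision.

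The genes named were fixed by rule before the data were examined. For IAA and for the double mutant they are the 10 largest rises and the 10 largest falls among single-gene probe sets past the threshold and moving the same way in every pair of arrays. For the third genotype, the mock spray and the response difference the number is 5. Where fewer than 5 passed in a direction, the largest that changed at least 1.5-fold the same way in every pair are named as not past the threshold. Of the fixed lists, members past the test are named, and otherwise up to 4 with the largest difference. The 22 lists, with 294 entries, were also fixed beforehand. They cover Aux/IAA, GH3, SAUR, other auxin-inducible genes, the ARF family, jasmonate synthesis and response, stamen and petal MYB factors, floral volatile terpene synthases, cell wall expansion, floral organ identity, class 1 KNOX and boundary genes, gibberellin, flavonoid synthesis, touch and wound response, ethylene, and markers of pollen, tapetum, dividing cells, green tissue, nectary and senescence. Only 45 entries lay on named probe sets and 26 passed the filter, so 8 lists had 2 or more genes and could be tested. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated one. Their medians in single pairs of arrays were set against 10000 random lists matched on intensity.

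The test was tried on simulated data with 200 changed probe sets among 13021. For IAA it recovered 87% of 2-fold and 99% of 4-fold changes with 7.46% false calls, for the double mutant 70% and 100% with 4.49%, for the third genotype 70% and 98% with 8.20%, and for the mock spray 22% and 93% with 3.36%. For the response difference it recovered 0% at either size. The simulated noise came from the variance prior of the fit, was equal on all arrays for a probe set, and the effects were exactly additive. These rates hold for that setting and were not measured on the real arrays. Alternatives to the normalization, floor, filter, probe set type, variance prior, control array and included arrays were listed before the data were examined, and their effect is in the closing section.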

Results

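Flowers of wild type and of 2 arf6 arf8 mutant genotypes were profiled on 7 arrays to ask how auxin alters flower transcripts and how this depends on ARF6 and ARF8. Every group holds 1 array, so values per array are given without an error. The median intensity was between 241 and 261.5 on the 7 arrays. The wild-type mock array had a raised low end. Its 10th percentile was 26.9 against 9.4 to 17.89 on the other arrays, and 27 control probe sets for bacterial transcripts had a median of 28.1 against 5.2 to 15.9.

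IAA against untreated flowers was compared over the 3 genotypes. The homeobox gene HAT2, a known auxin-inducible gene, was 2.49-fold higher with IAA, and GH3.3, which encodes an enzyme that conjugates IAA to amino acids, was 2.31-fold higher (limma, adjusted p = 0.0111 and 0.0214). HAT2 read 717.5 on the wild-type mock array against 881.7 untreated and 2111.9 with IAA, and GH3.3 read 829.8, 725.1 and 2011.6 on the same arrays. In the double mutant HAT2 went from 1321.3 to 3942.4 and GH3.3 from 539.9 to 955. EXO, a growth-related gene also known to respond to brassinosteroids, rose 3.24-fold, and the cold-regulated COR27 rose 2.89-fold (limma, adjusted p = 0.00985 and 0.0102). For these genes the mock array lay near the IAA array: EXO read 5650.4 with mock and 6699.1 with IAA in wild type, and COR27 791.4 and 777.1.

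**Figure D1:**
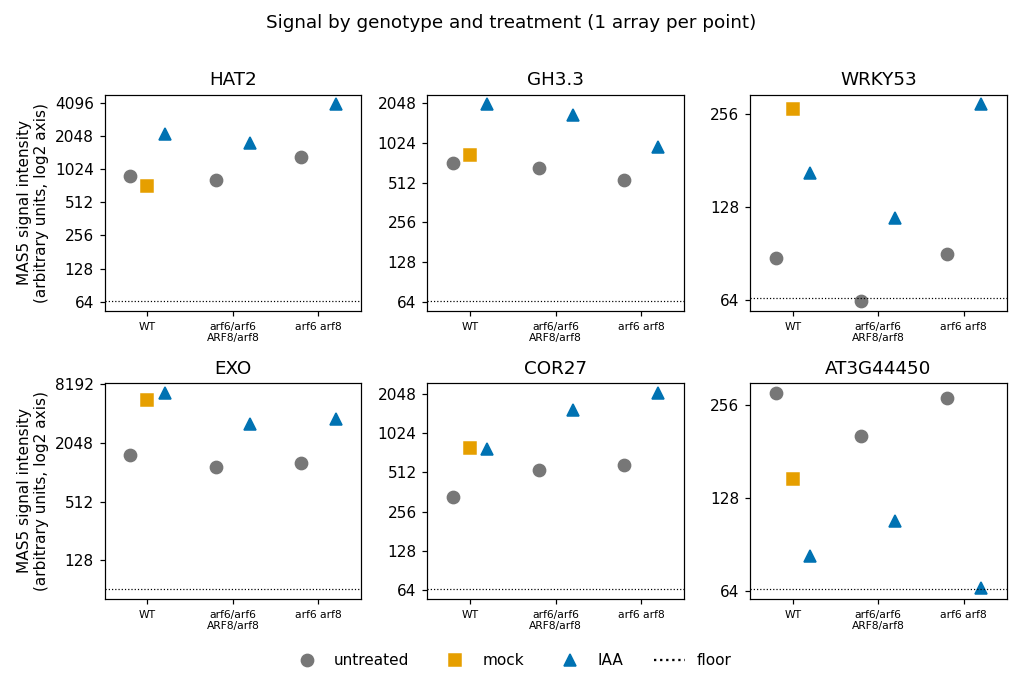
MAS5 signal intensity (log2 axis) of 6 genes on each of the 7 arrays by genotype, with 1 point per array and the floor of 64.9 dotted. In wild type the mock array of HAT2 (717.5) and GH3.3 (829.8) lies near the untreated array, while that of EXO (5650.4) and COR27 (791.4) lies near the IAA array.

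Over all probe sets 141 differed with IAA, 96 higher and 45 lower, and 63 of them carry 1 gene. The other named rises were AT1G72900 at 4.07-fold, AT1G50040 at 3.31-fold, AT4G27280 at 2.98-fold, AT3G19680 at 2.85-fold, AT3G46600, which encodes a GRAS-family protein, at 2.65-fold and BZIP61 at 2.27-fold (limma, adjusted p from 0.00642 to 0.0186). The named falls were AT3G44450 at 2.96-fold, the cytochrome P450 gene CYP71B26 at 2.28-fold, AT1G48100 at 2.24-fold, the glycosyltransferase gene AT1G06000 at 2.06-fold, AT1G01250 at 1.99-fold, the vacuolar processing enzyme gene BETA-VPE at 1.93-fold, AT2G23840 at 1.90-fold, the HSP70 gene AT3G09440 at 1.86-fold, the nitrate transporter gene AT3G21670 at 1.83-fold and AT1G69730 at 1.80-fold (limma, adjusted p from 0.0153 to 0.0367). Without either double-mutant array limma called 0 probe sets, with 1639 at an unadjusted p under 0.05, and each named gene kept its direction at an adjusted p between 0.109 and 0.187; without the wild-type untreated or IAA array the count was 281. With untreated and mock as one control limma called 2, and against the mock array, a contrast added after the data were seen, 23, of which 5 are among the 141. With no filter limma called 0 (2429 at an unadjusted p under 0.05), with a filter at the 70th percentile 236 and with an intensity trend 380. With a floor at the 40th percentile it called 52 and 10 of the named genes lost the call, among them GH3.3 (limma, adjusted p = 0.0503) and AT1G50040 (log2 0.57, adjusted p = 0.145). Without either array of the third genotype AT2G23840, AT3G09440 and AT3G21670 lost it (limma, adjusted p from 0.0578 to 0.068).

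In wild type these calls were set against the single mock array. Of the 96 higher probe sets, 65 were at least 1.5-fold higher with mock than untreated and 22 at least 1.5-fold higher with IAA than with mock, with 5 in both sets. Of the 45 lower ones the numbers were 32 and 7, with 1 in both. The untreated wild-type array enters both the calls and the mock ratio, which by itself makes them move together. Likewise the wild-type IAA array enters both the calls and the ratio of IAA over mock, with the same effect. The mock array, which has the raised low end, enters both ratios in opposite directions. A high mock value alone raises the ratio of mock over untreated and lowers that of IAA over mock. The small number in both sets is therefore partly built into the comparison. A rule set after the data were seen named the single-gene calls at least 1.5-fold the same way over mock: HAT2, GH3.3, AT4G27280, CML41, AKINBETA1, AT1G23030 and AT1G49200 among the rises, and AT3G56290 and AT3G44450 among the falls. CML41, a calmodulin-like gene, rose 2.14-fold, and AKINBETA1, a subunit gene of a SNF1-related kinase, rose 1.82-fold (limma, adjusted p = 0.0367 and 0.0214).

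**Figure D2:**
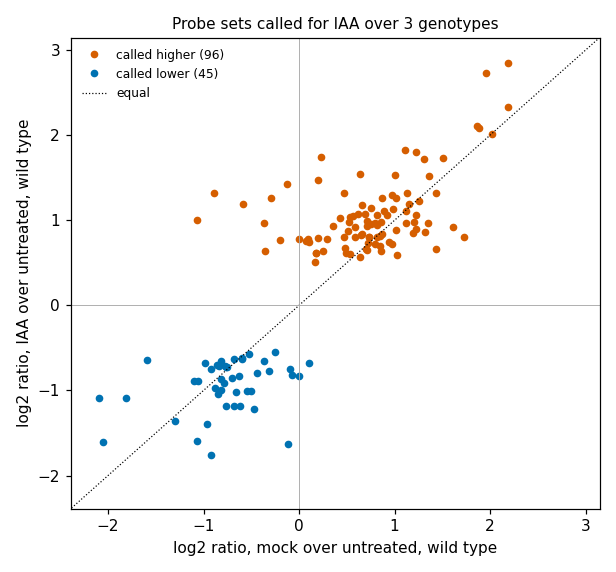
Each point is 1 of the 141 probe sets called for IAA, with the log2 ratio of mock over untreated in wild type on the horizontal axis and IAA over untreated on the vertical axis. Of the 96 called higher, 65 were at least 1.5-fold higher with mock, and the dotted line marks equal ratios; both axes use the same untreated array.

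Among the auxin lists, GH3 had 3 measured members, of which GH3.3 rose past the test over all genes and 2 did so adjusted over the list alone. GH3.5 and GH3.17 had fitted log2 differences of 0.35 ± 0.13 and 0.35 ± 0.18 (SE). The log2 ratio of GH3.5 with IAA over untreated was 0.14 in wild type, 0.3 in the third genotype and 0.61 in the double mutant. For GH3.17 it was 0.11, 0.05 and 0.9 in that order. The GH3 list was shifted up (camera, adjusted p = 0.00799), and not with an estimated correlation (adjusted p = 0.638). The 2 measured members of the touch and wound list, WRKY53 and STZ, were shifted up (camera, adjusted p = 0.0115), with adjusted p = 0.658 for an estimated correlation. WRKY53, a stress-related transcription factor gene, rose with IAA (log2 1.13 ± 0.17, limma adjusted p = 0.0348) and was higher on the mock array (1.72 ± 0.26, adjusted p = 0.0467). For STZ, a zinc finger gene, the IAA value was 0.91 ± 0.36 (limma, adjusted p = 0.29). Its log2 ratio was 0 in wild type, 0.56 in the third genotype and 2.16 in the double mutant. In single pairs of arrays, 5 of 24 list medians of IAA against untreated lay outside the central 95% of the random lists, as did 1 of 8 for IAA against mock, 1 of 8 for mock against untreated and 17 of 32 for a mutant against wild type. For GH3 the percentile was 84.5 in wild type, 95.9 in the third genotype and 99.9 in the double mutant for IAA against untreated, and 90.2 for IAA against mock. No gene of the ARF, SAUR, class 1 KNOX and boundary, ethylene, green tissue, or stamen and petal MYB lists is named here. Of the Aux/IAA list IAA18 was measured, at 0.22 ± 0.11 (limma, adjusted p = 0.4).

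The mock spray against untreated in wild type gave 57 probe sets higher and 41 lower, and 50 and 86 after quantile normalization. The mock array has no repeat, and these p-values assume that it varies like the other 6 arrays, although it is the one with the raised low end. The named rises were AT4G31030 at 5.45-fold, AT3G18840 at 4.51-fold, AT3G13630 at 4.39-fold, AT2G37780 at 4.29-fold and AT5G39560, below the floor when untreated, at least 4.12-fold by the arrays' ratio (limma, adjusted p from 0.0219 to 0.0413). The named falls were AT4G03100 at 4.87-fold and AT5G26110 at 3.57-fold, and by the arrays' ratio AT3G02320 at least 4.35-fold, AT1G48100 at least 4.26-fold and AT3G14750 at least 3.63-fold, which were below the floor with mock (limma, adjusted p from 0.0227 to 0.0418). The 2 measured genes of the touch and wound list had a mean log2 difference of 1.294 with mock, against 1.019 with IAA over the genotypes. With mock this did not pass the test (camera, adjusted p = 0.122), but the median standard error over all probe sets was larger there, 0.191 against 0.1208. In wild type the list median was 1.017 for mock over untreated (percentile 98.1 of the random lists). For IAA over mock it was -0.552 (percentile 13.8). With a floor at the 10th percentile limma called 32 probe sets and 5 of the named genes lost the call; with a floor at the 40th it called 0 (2141 at an unadjusted p under 0.05), with a filter at the 70th percentile 4, with an intensity trend 30 and with no filter 906. Without either double-mutant array it called 0 (2533 at an unadjusted p under 0.05), with adjusted p from 0.0809 to 0.0979 for the named genes; without wild-type untreated it called 257, without wild-type IAA 191 and without either array of the third genotype 238.

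The double mutant was set against wild type over the untreated and the IAA pair. SWEET9, the sucrose transporter of the nectaries, fell 19.4-fold, from between 1460.6 and 1781.9 on the 3 wild-type arrays to 82.6 and 83.5 (limma, adjusted p = 3.28e-05). TPS11, a flower sesquiterpene synthase gene, fell by 2.58 ± 0.15 on the log2 scale, and TPS24, a monoterpene synthase gene, was at least 7.07-fold lower, with both double-mutant arrays below the floor (limma, adjusted p = 0.000249 and 0.000114). EXPA8, which encodes a wall-loosening expansin, fell by 3.04 ± 0.22 (limma, adjusted p = 0.000484). Tapetum and pollen markers moved in opposite directions: the tapetum gene A9 was higher by 1.48 ± 0.24 and the pollen gene AT59 fell by 1.09 ± 0.17 (limma, adjusted p = 0.00901 and 0.00815).

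**Figure D3:**
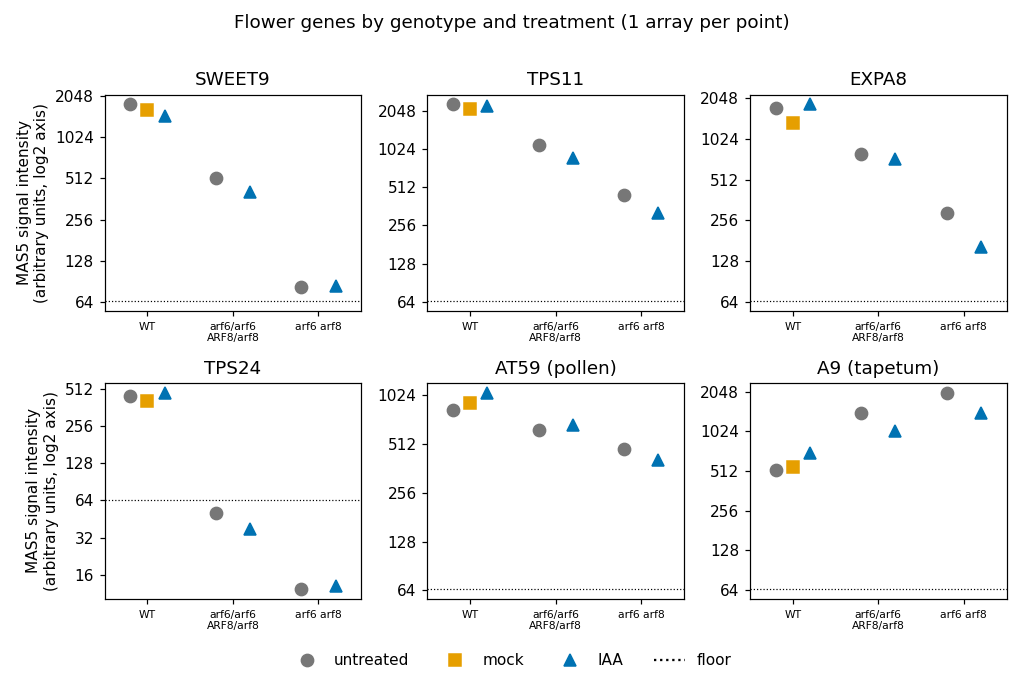
MAS5 signal intensity (log2 axis) of 6 flower genes on each of the 7 arrays by genotype, with 1 point per array and the floor of 64.9 dotted. SWEET9 goes from 1781.9 untreated in wild type to 518.9 in the third genotype and 82.6 in the double mutant, and the tapetum gene A9 goes from 517.6 to 1401.3 and 2011.4.

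In all 2227 probe sets differed, 1190 higher and 1037 lower, and 1175 of them carry 1 gene. The other named falls were AT3G12000 at 12.8-fold, AT5G11420 at 12.0-fold, AT4G19430 at 10.8-fold, the pectate lyase gene AT5G48900 at 8.68-fold and the lipid transfer protein gene AT1G05450 at 8.48-fold. Both double-mutant arrays were below the floor for the Kunitz-type inhibitor gene AT1G72290, at least 12.7-fold lower, for AT1G30795, at least 10.1-fold, for AT1G70720, at least 8.45-fold, and for AT1G72110, at least 8.34-fold. For these falls limma's adjusted p was between 0.000125 and 0.000615. The named rises were AT3G53980, of the lipid transfer protein family, at 15.2-fold, the expansin-like gene EXLB1 at 9.36-fold, AT1G16950 at 6.83-fold, AT1G33055 at 6.16-fold, AT1G62510 at 4.63-fold, AT4G35690 at 3.97-fold, AT2G21560 at 3.88-fold and the linker histone gene HIS1-3 at 3.76-fold. The thionin gene THI2.2 and the cyclophilin gene AT3G55920 were below the floor on every wild-type array and at least 6.46-fold and 4.43-fold higher. For these rises limma's adjusted p was between 5.38e-05 and 0.00959, and THI2.2 had 0.0507 without the untreated and 0.119 without the IAA array of the double mutant. Scaling to a common median of bright probe sets gave 1047 higher and 1118 lower. Without the double-mutant IAA array the count was 621, without the wild-type IAA array 1195 and with no filter on dim probe sets 2.

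Of the lists, cell wall expansion had 3 measured members, and 2 fell, EXPA8 and XTH33 (log2 -1.08 ± 0.16), with EXPA15 at -0.46 ± 0.17. All 3 passed when adjusted over the list alone (camera, adjusted p = 0.0031 for the list). Both terpene synthases fell (camera, adjusted p = 0.000544), as did both pollen genes AT59 and ANX2 (-1.48 ± 0.25; camera, adjusted p = 0.0158). The tapetum genes A9 and AMS (0.85 ± 0.19) both rose (camera, adjusted p = 0.0428). For each of these 4 lists the estimated correlation gave adjusted p = 0.313. Of GH3, GH3.5 rose by 1.02 ± 0.16 and GH3.17 and GH3.3 fell by 1.14 ± 0.22 and 0.75 ± 0.18 (limma, adjusted p = 0.00774, 0.0168 and 0.0346). HAT2 rose by 0.74 ± 0.16 and the carpel gene SPT by 0.73 ± 0.14 (limma, adjusted p = 0.0227 and 0.016). In jasmonate synthesis OPCL1 and AIM1 had values of -0.61 ± 0.17 and -0.42 ± 0.14; 0 passed over all genes and 2 adjusted over the list alone (camera, adjusted p = 0.0792). Not past the test were the jasmonate-responsive THI2.1 at 0.17 ± 0.13, the gibberellin receptor gene GID1A at 0.42 ± 0.17, the flavonoid genes DFR and UGT78D2 at 0.05 ± 0.40 and -0.03 ± 0.16, the division marker AUR1 at -0.09 ± 0.16 and the senescence marker SAG29 at 0.15 ± 0.26.

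The third genotype against wild type gave 149 probe sets higher and 211 lower. TPS24 was at least 7.07-fold lower, and TPS11, SWEET9 and EXPA8 fell by 1.21 ± 0.15, 1.81 ± 0.15 and 1.24 ± 0.22 on the log2 scale (limma, adjusted p = 0.000801, 0.0162, 0.00744 and 0.0383). The other named falls were AT1G43590, at or below the floor on both arrays of the third genotype, at least 6.21-fold, AT5G64120 at 5.95-fold, AT3G54240 at 5.86-fold and AT5G47350 at 4.44-fold. The named rises were AT3G53980 at 5.70-fold, AT5G44440 at 3.75-fold, AT1G72290 at 3.72-fold, EXLB1 at 3.59-fold and AT4G11210 at 3.56-fold. For these falls and rises limma's adjusted p was between 0.00305 and 0.0231. AT1G72290 and AT3G54240 had adjusted p = 0.0678 and 0.0927 with a floor at the 10th percentile, and EXLB1 0.0723 with a floor at the 40th (limma). The lists of cell wall expansion, terpene synthases, pollen and tapetum had the same direction of shift as in the double mutant (camera, adjusted p = 0.0038, 7.65e-05, 0.0203 and 0.0242), and with an estimated correlation their adjusted p was 0.346 or 0.393. For pollen and tapetum 0 members passed over all genes, and 2 of each did adjusted over the list alone. Without the third genotype's untreated array the count of 360 was 119, without its IAA array 216, and without a double-mutant array 144. It was 1 with no filter, 216 with a floor at the 40th percentile, 578 with a filter at the 70th percentile and 822 with an intensity trend.

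The mutants shared 135 of the higher calls and 202 of the lower calls, where independent lists of these sizes would share 13.6 and 16.8. Both comparisons use the same wild-type arrays, so the value for independent lists is not a full baseline. Simulated unchanged groups shared 0.25 calls on average. Such groups give few calls at all, so they cannot show how much sharing the common arrays add among real calls. The fitted differences correlated across probe sets with r = 0.788, against 0.497 in the simulation, and their covariance was 0.148 against 0.0136. From pairs with no shared array r was 0.529 and 0.629. Probe sets are not independent replicates. Of the shared calls, 93 of the 135 higher and 160 of the 202 lower ones differed less from wild type in the third genotype than in the double mutant.

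Whether the response to IAA differed in the double mutant was tested with the term for IAA in that genotype. No probe set passed (limma, smallest adjusted p = 0.405), 1461 had an unadjusted p under 0.05, and simulated 4-fold differences were not recovered, so this test could not show a difference of that size. The fitted differences of the response were -0.58 ± 0.19 for GH3.3 and 0.39 ± 0.19 for HAT2. The values largest by rule, none past the threshold, were STZ at 1.88 ± 0.29, AT2G38840 at 1.81 ± 0.46, TRY at 1.74 ± 0.19, AT5G24980 and AT4G00700 among the higher, and AT1G75200 at -1.90 ± 0.31, AT4G30940, AT2G26520, AT2G39980 and AT1G60230 among the lower, each of which was below the floor on the double-mutant IAA array. Of these 5, AT1G75200, AT2G26520 and AT1G60230 were also lower with mock than untreated in wild type, by log2 ratios of -2.50, -1.85 and -1.65, against -2.22, -1.68 and -1.96 or further from 0 with IAA in the double mutant. In wild type TRY had a ratio of -0.95 with IAA and of -0.78 with mock. The mock and the double-mutant IAA array also had the lowest scores on PC2 of a principal component analysis, -21.57 and -22.21, against -2.31 to 18.4 on the other arrays. The touch and wound list, STZ and WRKY53, was shifted up (camera, adjusted p = 0.0147; with an estimated correlation adjusted p = 0.979). Over the 96 probe sets at least 2-fold higher with IAA in the third genotype, the median log2 ratio was 0.847 in wild type and 0.891 in the double mutant. Over the 47 at least 2-fold lower, it was -0.476 and -0.838. With mock as the wild-type control the wild-type medians were 0.203 and 0.041. Over all probe sets the log2 ratios of IAA over untreated spread more in the double mutant (SD 0.412) than in wild type (SD 0.290). There 162 were over 2-fold higher and 161 lower in the double mutant, against 88 and 32 in wild type. Whether this wider spread accounts for the larger double-mutant medians was not tested.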

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

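The tests of the mock array were chosen after the results were seen; the test of the response difference was not.

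AT1G72290, AT3G10020 and an unnamed probe set were called in both mutants in opposite directions. The double mutant minus the third genotype was -2.17 on the log2 scale for AT3G10020. For AT1G72290 and the unnamed probe set both double-mutant arrays were below the floor, so the values of -5.56 and -3.21 are the smallest sizes these differences can have. Limma's test of this difference gave adjusted p = 0.00379 for AT3G10020, 6.14e-05 for AT1G72290 and 0.00322 for the unnamed probe set, but the opposite calls chose these probe sets, so it adds no evidence to those calls. AT1G72290 read 690.1 untreated in wild type, 3148.3 in the third genotype and 15.5 in the double mutant.

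The single-gene probe sets with a ratio of IAA over untreated of at least 1.5-fold in one direction in wild type and the third genotype, and of at least 1.5-fold in the opposite direction in the double mutant, were TRY, 4CL8 and AT5G66180. Their differences of the response were 1.74, 1.60 and -1.30 on the log2 scale, and none passed the test (limma, adjusted p = 0.405 for each). TRY, a repressor of trichome formation, had log2 ratios of -0.95, -1.08 and 0.72, and mock over untreated in wild type gave -0.78, near its wild-type ratio with IAA. The mock ratios of 4CL8 and AT5G66180 were -0.06 and -0.24.

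Bacterial control probe sets, which should find no transcript in these samples, had a median of 28.1 on the mock array and 8.3 on the untreated wild-type array. If that array alone made the 211 probe sets at least 2-fold higher with mock, they would not be higher with IAA in the mutants, which share no array with that pair. Their median log2 ratio was 0.28 in the third genotype, at percentile 100 of 2000 random lists matched on intensity, which argues against the mock array alone; the bacterial controls there read 8.7 with IAA and 11.1 untreated, while in the double mutant (median 0.592) they read 15.9 and 5.2, so that value can carry a raised low end too. For the 123 probe sets at least 2-fold lower with mock, that median was -0.116 in the third genotype, at percentile 0.05, which argues the same way; both medians are well under 2-fold, so a share of either set may still come from the mock array. A response to the spray stays open for both parts, since the sprayed mutant arrays also held IAA.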

How the results depend on the processing

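Alternatives were planned before the data were examined, except IAA against the mock array and leaving out the double-mutant pair. Where no cause is given, the cause was not tested. Without a filter, 3379 of 22746 probe sets lie at the floor on all 7 arrays and have no variance; limma's counts were then 0 for IAA (2429 at an unadjusted p under 0.05), 2 for the double mutant, 1 for the third genotype and 906 for mock. With a floor at the 40th percentile they were 52 for IAA, 216 for the third genotype and 0 for mock, and with a floor at the 10th 32 for mock. With a filter at the 70th percentile they were 236 for IAA, 578 for the third genotype and 4 for mock, and with an intensity trend in eBayes 380, 822 and 30 in that order. Quantile normalization turned the mock split of 57 higher and 41 lower to 50 and 86. IAA gave 2 calls with untreated and mock as one control, 23 against the mock array and 0 without the double-mutant pair. Leaving out each array gave 0 to 281 for IAA, 621 to 2227 for the double mutant, 119 to 363 for the third genotype and 0 to 257 for mock. Of 40 list tests 11 passed, 6 without a filter and 0 with an estimated correlation. For genes chosen in the third genotype at 1.5-fold, the medians of the higher set were 0.361 in wild type and 0.567 in the double mutant and of the lower set -0.19 and -0.447; at 3-fold 1.727, 1.844, -0.744 and -1.606. With mock as control the wild-type medians were 0.203 and 0.041, the latter turned in sign. The response count by limma was 0 in every alternative run (704 to 3437 at an unadjusted p under 0.05). Leaving out a wild-type array other than mock, or an array of the third genotype, left no residual degrees of freedom. Without either double-mutant array the response difference could not be estimated. Of 629 alternatives on 70 named results, 533 kept call and direction, 96 lost the call and 0 turned. Not all of these are separate trials. Leaving out the mock array cannot change the IAA or genotype differences, because that array has its own term. Leaving out either array of a genotype's untreated and IAA pair gives the same IAA difference. The named response results had no call to lose. The count of 533 therefore overstates how robust the calls are. The alternative for ARF6 and ARF8 was not run, as neither is named here. No paired analysis was possible because each group holds 1 array and so 1 replicate number; the genotype term of the fit already compares arrays within a genotype. Signal near the floor limits dim probe sets.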

Other observations

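The gene groups and the tests in this part were chosen after the data were seen, and the counts in it rest on 1 array per group. Among 30 families defined by a shared symbol, and the plastid-encoded genes counted among them, cellulase-like GH9 genes were lower in the double mutant: 6 of 9 fell and 1 rose (camera, adjusted p = 0.00335; adjusted p = 0.528 with an estimated correlation). GH9B11, below the floor on both double-mutant arrays, had a log2 difference of -2.83 or further from 0, GH9C2 fell by 1.77 ± 0.15 on the log2 scale and GH9A4 by 1.34 ± 0.14, and GH9B18 rose by 0.91 ± 0.18. In the third genotype 3 of the 9 fell, GH9B11 by 1.63 ± 0.15 (camera, adjusted p = 0.00248; adjusted p = 0.573 with an estimated correlation). Of 5 alpha-expansin genes, 3 fell in the double mutant, EXPA8, EXPA4 (-0.83 ± 0.14) and EXPA24 (-0.80 ± 0.20) (camera, adjusted p = 0.00179; adjusted p = 0.528 with an estimated correlation).

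Of 66 plastid-encoded genes 7 fell in the double mutant, petG by 1.38 ± 0.14, and the set had a median of -0.254 (camera, adjusted p = 5.47e-06, and 0.528 with an estimated correlation). Over all probe sets 1037 of 13021 were called lower in the double mutant, so the 7 of this set are near the overall share. With IAA the set had a median of 0.173, and ndhH rose past the test by 0.70 ± 0.11 (camera, adjusted p = 1.38e-07; adjusted p = 0.856 with an estimated correlation). With mock the median was 0.177 (camera, adjusted p = 0.429), and ndhH read 271.7 untreated, 409.9 with IAA and 550.8 with mock in wild type. Among autophagy genes ATG8F and ATG8B rose in the double mutant by 0.95 ± 0.13 and 0.73 ± 0.13 (camera for the 8 genes, adjusted p = 0.0492; adjusted p = 0.528 with an estimated correlation). Of 8 RALF-like peptide genes, RALFL25, RALFL26 and RALFL24 fell there by 1.82 ± 0.14, 0.75 ± 0.14 and 0.64 ± 0.15 and RALFL28 rose by 1.45 ± 0.18, and the set as such did not pass (camera, adjusted p = 0.117). In the third genotype the RALF-like set was shifted down (camera, adjusted p = 0.0387, and 0.573 with an estimated correlation), and 1 gene, RALFL25, fell by 0.93 ± 0.14. There the plastid-encoded genes (camera, adjusted p = 0.000179) and the alpha-expansin genes (camera, adjusted p = 0.0196) were also shifted down. So were the TUB and BZIP families (camera, adjusted p = 0.0196 and 0.0198). With an estimated correlation camera gave adjusted p = 0.678 for the plastid-encoded genes and 0.573 for the others. The medians of the GH9, alpha-expansin, plastid-encoded, autophagy and RALF-like sets for IAA and for both mutants kept their sign under quantile normalization. So did that of the plastid-encoded genes for mock. They also kept it under scaling to a common median, which moves all log2 differences of a contrast by about the same amount. That amount was smaller than each of these medians, so this part of the check could not turn a sign.

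How much of the IAA response is a response to the spray was asked on probe sets chosen without a wild-type array. For the 40 at least 2-fold higher with IAA in both mutants, the wild-type median was 1.21 with IAA and 0.979 with mock over untreated, and 0.382 with IAA over mock. For the 17 lower ones it was -0.825, -0.766 and -0.194. The medians of IAA over mock lay at percentiles 100 and 2.35 of 2000 matched random lists, so a part beyond the spray stays open in both directions. The mock medians lay at percentiles 100 and 0, which is consistent with the spray itself changing many of these transcripts, as a hypothesis, while HAT2 and GH3.3 had log2 ratios of mock over untreated of -0.30 and 0.19.

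The split of the 6 untreated and IAA arrays by treatment gave 141 calls and the highest of the other 9 splits gave 0. With 10 splits in all, of which 1 was as large, a share under 0.05 cannot be had. The other splits are also not equal comparisons. Those that keep both arrays of a genotype together rest on the pair of 1 genotype. An IAA difference adds to the residual spread of the other splits, which can lower their calls.

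For the double mutant, a uniform loss of all flowers that hold mature pollen was considered. It would lower nectary and pollen genes by the same factor if they were expressed in those flowers alone, which was not tested. SWEET9 fell further than the pollen genes AT59 and ANX2, by log2 differences of -3.19 ± 0.23 and -2.798 ± 0.291. This argues against such a loss under that assumption only. A loss of the latest stages alone was not tested and stays open. A graded effect of the number of functional copies was asked on probe sets chosen with the IAA arrays: for 442 higher and 560 lower ones, the untreated median of the third genotype was a share of 0.486 and 0.568 of that of the double mutant, which is consistent with a graded effect as a hypothesis; the untreated wild-type array enters both medians. Of the 1160 called genes with a position, 95.9% lay outside 300 genes on each side of ARF6 and of ARF8. Passenger differences within these windows therefore cannot make up most of the changes. The windows held 143 and 98 of the tested genes with a position, so most genes lie outside them, called or not. Passenger differences in a wider linked segment were not tested. Near ARF6, 8 of 37 genes within 100 genes were called against 1152 of 6798 elsewhere, and near ARF8 5 of 27 against 1155 of 6808 (Fisher's exact test, smallest adjusted p = 0.86 over both windows in the double mutant). In the third genotype 4 of 37 genes near ARF6 were called against 192 of 6798 elsewhere (Fisher's exact test, p = 0.0207, adjusted p = 0.166 over all 8 tests). For these few neighbours linked differences cannot be told apart from an effect of the genotype, and an effect of a linked variant on distant genes was not tested.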
